A study of Drosophila melanogaster with 82 samples.

How the data were processed

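Translating messenger RNA was measured in 7 tissues of adult female Drosophila melanogaster on either of 2 foods, with 82 arrays in 14 groups of tissue and food. Per the labels, each fly line carried a tissue-specific GAL4 driver that switched on a FLAG-tagged copy of the ribosomal protein RpL13A, and ribosomes with their bound messages were pulled down with FLAG antibody beads. Flies were moved to rich food (AL, 5% yeast extract) or to restricted food (DR, 0.5% yeast extract) soon after eclosion, kept there for 10 days and collected at an age of 13 days, per the labels' protocols. A pool held about 100 flies, or 200 for the neuron line. Each array holds 1 pool, so a replicate is a separate pool of flies. Each group has 6 pools, apart from heart AL and neuron AL with 5.

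Per the labels' protocols, the authors amplified the pulled-down RNA with a whole-transcriptome kit, labelled it with Cy3 and hybridised it to single-colour NimbleGen oligonucleotide arrays, and they spread the pulldowns, amplifications and labellings at random over the groups. The deposited values are linear probe intensities for 137098 probes, of which 132998 belong to 16637 transcripts (8 probes each for 16616 of them) and 4100 are random-sequence control probes. Within a tissue the sorted log2 intensities of each array as deposited differ from those of the tissue's first array by at most 0.04. The deposited values were therefore quantile normalized within each tissue. Between tissues they differ by up to 2.67. The scanner, the extraction software, any background correction and the annotation release are not given in the sources used here. No column of a sample outside the design was used.

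Intensities were taken to log2 and the probes of a transcript were averaged. Comparisons of the foods within a tissue used the deposited log2 values without further scaling. Comparisons between tissues used a quantile normalization over all 82 arrays, which assumes that the tissues share 1 distribution of levels. All arrays entered 1 linear model of the 14 groups in limma 3.58.1 (R 4.3.3, with version 1.17.8 of data.table), with 68 residual degrees of freedom before the empirical Bayes moderation. Each tissue's DR minus AL difference was tested with limma's moderated test, the differences between the 7 tissues' diet effects with a moderated F test, and the mean of the 7 effects with a moderated test. P-values were adjusted by the method of Benjamini and Hochberg over all 16637 transcripts of a contrast, and an adjusted p below 0.05 was counted as a call. A transcript was counted as enriched in a tissue where its mean over both foods exceeded the mean of the other 6 tissues by at least 2-fold with an adjusted p below 0.05. No transcript was left out for a low level. Tests are two-sided. Figures were drawn with Python 3.11.15, numpy 2.4.6 and matplotlib 3.10.9.

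The table holds transcript identifiers and no gene names. The gene table used here (assembly Release 6 plus ISO1 MT, used for names alone) pairs 16 of the 16637 transcripts with 1 gene, of which 14 have a symbol beyond a bare CG number. It pairs 28 transcripts with several genes, which stay unnamed, and the other 16593 with none. The lists of pathway genes and cell type markers fixed before the data were examined, the test of those lists, and the genes Thor, InR, foxo and RpL13A were therefore not analysed here. The design, the comparisons, the first set of alternatives and the rule for named genes were chosen before the data were examined. That rule takes, per tissue, up to 5 symbols that rise and 5 that fall with every DR pool on one side of every AL pool, the 10 with the strongest tissue difference among those changed at least 2-fold somewhere, and up to 10 called alike in at least 4 tissues. With 14 symbols in all, each of them is described, whether it passed or not. Of unnamed transcripts, at most 2 that rose and 2 that fell are printed per comparison, taken by the size of the change among those with separated pools. A value belongs to 1 transcript identifier, and its probes may also match other transcripts of the gene.

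In place of the gene lists, and chosen after seeing the data, each tissue was given a group of leading transcripts, whose mean level exceeded that in every other tissue by at least 2-fold and which were enriched there. These groups were chosen on the same arrays, so their changes are not independent evidence of direction. Their diet changes were tested with limma's camera at its preset correlation of 0.01 over 49 pairs of tissue and group, with an estimated correlation, with fry and by exact permutation of the pools. Fry asks whether the members of a group move, on balance, one way, and does not compare them with other transcripts.

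The 95th percentile of the control probes on an array marks the background. Where every array of a group lay below it for a transcript, the change is given as a bound, from the mean of the bright group against the mean background of the dim group's arrays. The share of transcripts above background ran from 62.8% ± 1.83 (SD, n = 6) in fat body AL to 95.4% ± 7.27 (SD, n = 6) in germ line DR, and the number of arrays limits the precision.

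The tests were run on simulated data with 200 of 16637 transcripts changed. Of those changed 1.5-fold, from 48% in gut to 66% in fat body were recovered, of those changed 2-fold from 82% in heart to 90% in germ line, and of those changed 3-fold at least 98% in every tissue. False calls ran from 3 in fat body and heart to 11 of 184 calls in tubule. The simulated noise was independent between transcripts, with 1 SD per transcript for all groups. In the real arrays the leading axis of variation within groups held 29.2% of the within-group variance, so these rates may not hold for the real calls. Alternatives to the scaling, the averaging of probes, a filter on dim transcripts, the samples in a fit, the moderation, array weights, the adjustment, a fold minimum and the pools included were all run, and so were covariates and probe subsets added after seeing the data. Pool numbers were tested as pairs, and random regroupings of the arrays were counted, 100 per result.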

Results

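The series asks whether the response to nutrients differs between tissues. Messages bound to tagged ribosomes were compared between flies on restricted food (DR) and rich food (AL) in the fat body, germ line, gut, heart, muscle, neurons and Malpighian tubule, the fly's organ of urine formation. Each tissue had 6 pools of flies per food, apart from heart and neuron with 5 AL pools. Every array measured 16637 transcripts. Changes are given as DR minus AL on the log2 scale with the standard error (SE), and adjusted p-values come from limma. A transcript called separated has every DR pool above every AL pool, or every one below. Chance gives this for 0.216% of transcripts with 6 against 6 pools and 0.433% with 5 against 6.

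Food changed the translating messages of every tissue. Transcripts passing the test numbered 6256 in fat body (3382 higher in DR, 2874 lower), 11807 in germ line (5685 higher, 6122 lower) and 5969 in gut (3006 higher, 2963 lower). Heart had 8687 (4174 higher, 4513 lower), muscle 9162 (4624 higher, 4538 lower), neuron 10977 (4725 higher, 6252 lower) and tubule 6624 (3399 higher, 3225 lower). Germ line had the most calls but the lowest share of separated transcripts, 16.2% of those tested, against 50.1% in neuron, the highest. A fit on germ line arrays alone gave 9747 calls (4185 higher, 5562 lower). Changes of at least 2-fold were fewer, from 858 in gut to 5474 in neuron. The median size of a called change was 0.58 in gut and 1.00 in neuron. With the dimmest 25% of transcripts left out, the calls in germ line were 2905 higher and 5984 lower, those in heart 2384 and 4284, and those in muscle 2832 and 4510. The median change of the transcripts tested then moved by -0.21, -0.10 and -0.14 in these tissues, and by -0.10 in neuron.

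**Figure D1:**
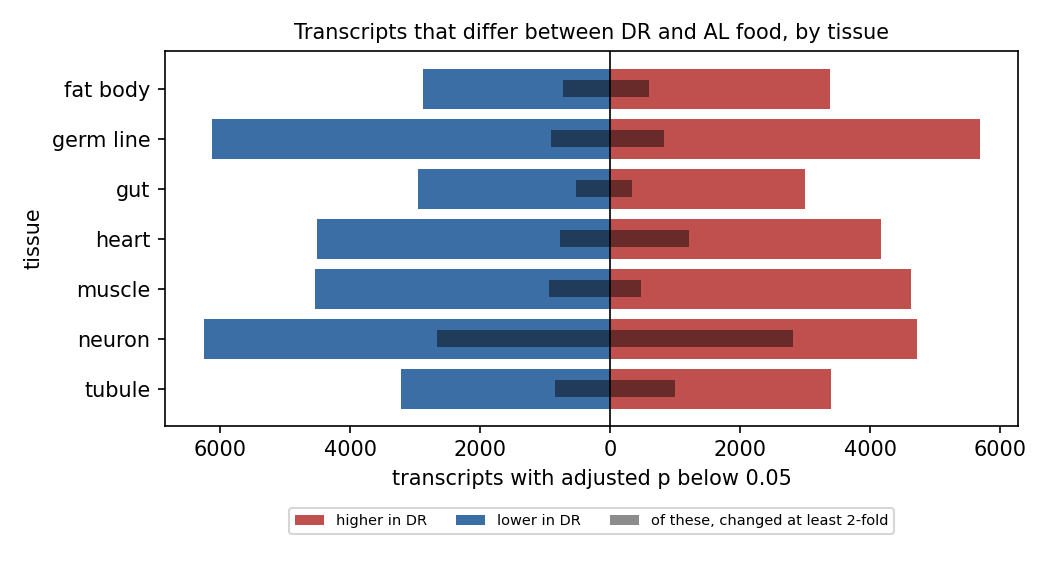
Bars give the number of transcripts with an adjusted p below 0.05 that were higher (right) or lower (left) on DR food in each of 7 tissues, and the inner grey bars those changed at least 2-fold. Neuron had 2807 transcripts at least 2-fold higher and 2667 at least 2-fold lower, and germ line had 11807 calls, of which 1735 reached 2-fold.

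A pair of transcripts, FBtr0089324 and FBtr0089326, fell on DR food in all 7 tissues. In germ line, where the fall of FBtr0089324 was smallest, it was 13.0-fold lower in DR than in AL, and in muscle it was 57.4-fold lower. In gut no DR array showed either above the control probes, which makes FBtr0089324 at least 80.5-fold and FBtr0089326 at least 64.4-fold lower. In tubule, again with no DR array above the control probes, the bounds were 49.4-fold and 40.3-fold. FBtr0082158 rose in all 7 tissues, by a mean of 2.36 (SE 0.10) and from 0.91 to 3.69 in single tissues. FBtr0088192 rose in all 7, by 0.91 in gut and by 4.37 in tubule. None of the 4 has a gene name in the table used here.

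In fat body, the insect counterpart of liver and adipose tissue, 6 of the 14 named genes rose on DR food and 3 fell (n = 6 pools per food). LanA, a laminin chain of basement membranes, rose 2.62-fold (1.39 ± 0.24 SE; adjusted p = 1.58e-06). The rise of mio was 1.76-fold (0.82 ± 0.12; adjusted p = 7.2e-08), and that of Wdr24 was 1.32-fold (0.40 ± 0.12; adjusted p = 0.00653). The products of mio and Wdr24 belong to GATOR2, a complex that acts on the growth kinase TORC1. The spectrin gene alpha-Spec, whose product lines the cell membrane, rose by 0.74 ± 0.15, Fatp1, a fatty acid transport protein, by 0.59 ± 0.16, and His4r by 0.31 ± 0.09. His4r encodes histone H4, which near-identical gene copies also encode, so its value is uncertain. All 6 rises were separated. The gene fend fell by 0.82 (SE 0.18), and HDAC3, a histone deacetylase, fell by 0.37 (SE 0.10), both separated. The gene sle fell by 0.54 (adjusted p = 0.0332), a call that was lost with quantile normalization over all arrays (-0.47, adjusted p = 0.0738) and when AL pool 2 or 4 or DR pool 1, 3, 4 or 5 was left out, with values from -0.70 to -0.45 over all pools left out. The rise of Wdr24 missed the threshold with the later probes of each transcript alone (adjusted p = 0.052). Among transcripts without a gene name, FBtr0082158 rose most, 12.9-fold (3.69 ± 0.26), followed by FBtr0072868 (3.40 ± 0.15).

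The 242 transcripts that led in gut fell in fat body by a median of 1.04. Of these, 182 fell and 5 rose (adjusted p = 0.0104 with an estimated correlation), and their mean level on the scale shared between tissues went from 11.14 ± 0.21 (SD, n = 6) in AL to 10.11 ± 0.21 (SD, n = 6) in DR. Members chosen from AL pools alone, 151 transcripts, gave a median of -0.58. In gut itself the same group had a median of -0.05 and did not pass (adjusted p = 0.488), with 53 higher and 60 lower. The 422 transcripts leading in fat body had a median of 0.39 there, with 193 higher and 46 lower (adjusted p = 1.38e-06, and adjusted p = 0.477 with an estimated correlation).

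In germ line none of the 14 named genes passed as higher on DR food and 8 fell (n = 6 per food). LanA missed the threshold at 0.50 (adjusted p = 0.0536) with separated pools, and passed as higher in the fit on germ line arrays alone (adjusted p = 0.00288), with cyclic loess (0.88, adjusted p = 0.00135) and under 5 other alternatives. Fatp1 (0.20, adjusted p = 0.233) passed as higher with cyclic loess (0.52) and with array weights (0.51). Values with array weights in this tissue rest mostly on DR pool 3, with a weight of 71.7 against at most 0.587 for the other DR pools. HDAC3 fell 1.66-fold (-0.73 ± 0.10 SE; adjusted p = 8.26e-09), with every DR pool below every AL pool. His4r fell by 0.52 (SE 0.09; adjusted p = 1.42e-06). The gene fend was lower by 0.98 ± 0.18 and the chromatin remodeller gene kis by 0.47 ± 0.10, and their values with the leading axis of variation within groups as a covariate were -0.34 (adjusted p = 0.117) and -0.19 (adjusted p = 0.171). That axis, taken over all tissues, correlated with the germ line diet change at -0.785 across transcripts, so the covariate may also remove an effect of food. The falls of the phosphate transporter gene NaPi-III (-0.48), of rdx (-0.34), a ubiquitin ligase adaptor, and of Wdr24 (-0.29) also ended under that covariate, at -0.25, -0.19 and -0.11, as did that of Uba1 (-0.17), the ubiquitin-activating enzyme, at -0.04. With the later probes of each transcript alone rdx was at -0.04 (adjusted p = 0.768) and Uba1 at -0.08 (adjusted p = 0.265). NaPi-III lost its call without DR pool 1, 2 or 3, rdx without DR pool 2 or 3, and Wdr24 without AL pool 2 or 4 or DR pool 4 or 5. Left-out pools moved NaPi-III between -0.55 and -0.42, rdx between -0.39 and -0.29 and Wdr24 between -0.34 and -0.26. Wdr24 was 0.035 with cyclic loess scaling. FBtr0087854 rose by 2.72 ± 0.11, the largest rise in this tissue.

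The gap in level between dim and bright transcripts narrowed on DR food in 6 tissues, most in germ line, heart, muscle and neuron. In germ line the mean change was 0.52 in the second decile of mean level and -0.39 in the seventh. In heart the corresponding means were 0.47 and -0.24, in muscle 0.42 and -0.29, and in neuron 0.15 and -0.33, against -0.03 and -0.01 in fat body. The largest mean rise lay in the fourth decile in neuron (0.44), but in the second decile in germ line, heart and muscle. The gap between dim transcripts (the lowest 3 deciles) and bright ones (deciles 6 to 8) narrowed on DR food by 0.83 (SE 0.13) in germ line, 0.61 (SE 0.14) in heart, 0.63 (SE 0.13) in muscle and 0.48 (SE 0.14) in neuron. These SEs pool the spread of all 14 groups, whose SDs ran from 0.015 in fat body AL to 0.59 in germ line DR. Exact permutation tests gave adjusted p = 0.0177 in germ line and muscle, where the pools overlapped. They gave adjusted p = 0.00505 in heart and neuron, where the pools were separated. It narrowed less in gut (0.14, exact permutation test, adjusted p = 0.0177) and tubule (0.16, exact permutation test, adjusted p = 0.00505, every DR pool above every AL pool). In fat body it did not pass (-0.01, exact permutation test, adjusted p = 0.84). The median level of the control probes was lower on DR food in heart (5.52 ± 0.16 SD, n = 5, against 5.20 ± 0.05 SD, n = 6; exact permutation test, adjusted p = 0.0152). The other 6 tissues' differences in that level had adjusted p-values of 0.0833 or more in exact permutation tests. For the 95th percentile of the control probes no tissue passed (exact permutation tests, adjusted p of 0.167 or more).

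**Figure D2:**
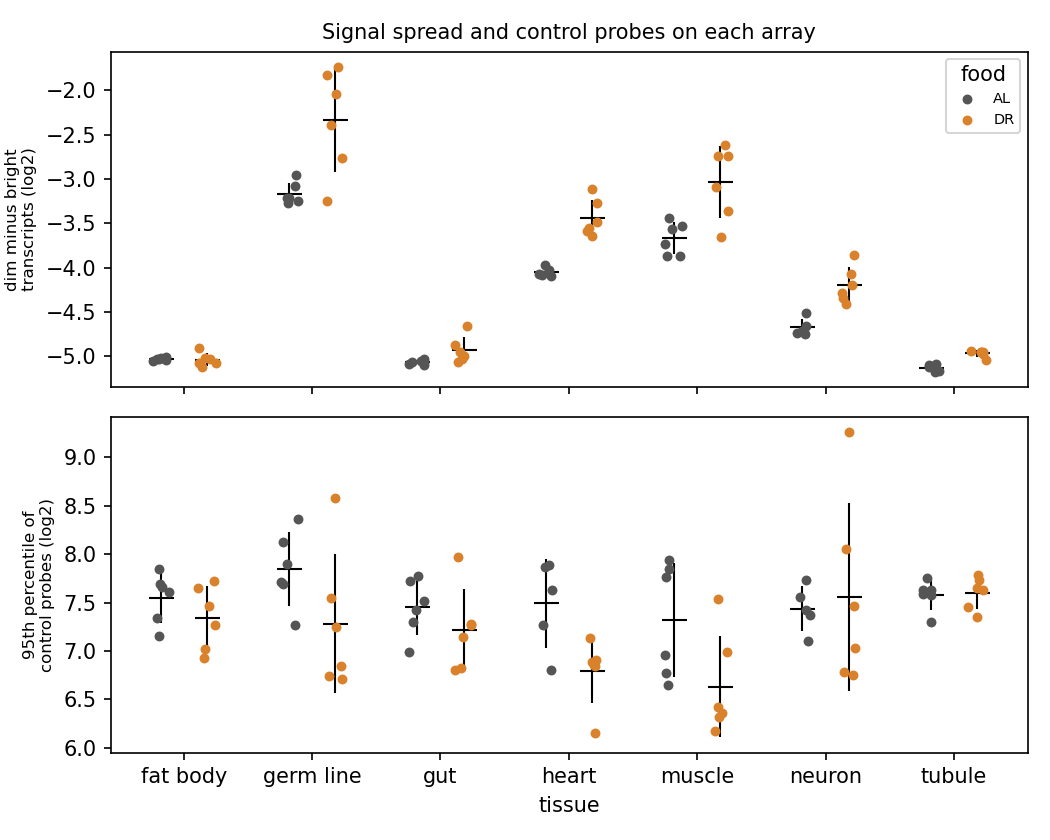
Each point is 1 array, with AL pools in grey and DR pools in orange, and black marks give the mean and SD of each group of 5 or 6. The upper panel plots the mean log2 level of dim minus bright transcripts, where DR pools lay higher by 0.83 in germ line, 0.61 in heart, 0.63 in muscle and 0.48 in neuron, and the lower panel the 95th percentile of the control probes on the log2 scale.

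In gut, LanA rose 1.82-fold (0.87 ± 0.24 SE; adjusted p = 0.00275; n = 6 per food) and alpha-Spec rose by 0.55 ± 0.15 with separated pools (adjusted p = 0.00172). These were the 2 named genes that passed as higher. The gene fend fell by 0.62 (SE 0.18; adjusted p = 0.00532). SuUR, named after a mutant in which underreplication of heterochromatin is suppressed, fell by 0.35 (adjusted p = 0.0247), and sle by 0.55 (adjusted p = 0.0323). Both of the latter calls were lost without AL pool 4 or DR pool 1 or 2, and that of sle also without AL pool 5 or DR pool 6. Values then ran from -0.42 to -0.27 for SuUR and from -0.67 to -0.37 for sle over all pools left out. SuUR was at -0.22 (adjusted p = 0.375) with later probes and sle at -0.19 (adjusted p = 0.228) with array weights, and in the fit on gut arrays alone sle had an adjusted p of 0.131. Among unnamed transcripts FBtr0082625 rose by 3.60 ± 0.25 and FBtr0087907 by 3.23 ± 0.21.

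In heart, alpha-Spec rose by 0.45 ± 0.15 with separated pools (adjusted p = 0.0101; n = 5 AL and 6 DR pools) and was the 1 named gene that passed as higher. LanA (0.35, adjusted p = 0.237) passed as higher in the fit on heart arrays alone (adjusted p = 0.00342), with array weights (0.29, adjusted p = 0.0366) and with cyclic loess (0.62, adjusted p = 0.0335). With each array's position slope and control probe level as covariates the change of alpha-Spec was 0.10 (adjusted p = 0.478). HDAC3 fell by 0.44 (SE 0.11; adjusted p = 0.000392), also separated, and was at -0.13 (adjusted p = 0.271) with the within-group axis as a covariate and at -0.17 (adjusted p = 0.0555) with cyclic loess. SuUR (-0.31, adjusted p = 0.0499) and Uba1 (-0.15, adjusted p = 0.0471) passed narrowly, and each lost its call under 9 of the 11 removals of a single pool, with values from -0.36 to -0.28 and from -0.18 to -0.13. With the within-group axis as a covariate SuUR was at -0.03 (adjusted p = 0.89) and Uba1 at -0.05 (adjusted p = 0.629), and SuUR was at -0.12 with cyclic loess, -0.13 with median polish and -0.23 with later probes. Uba1 was at -0.11 with median polish and -0.05 with later probes. SuUR kept its call without DR pool 2 or 6, and Uba1 without AL pool 5 or DR pool 2. FBtr0077042 rose most among unnamed transcripts (3.24 ± 0.24). The 72 transcripts leading in heart fell there by a median of 0.49 (35 lower, 8 higher; adjusted p = 0.000627, and adjusted p = 0.59 with an estimated correlation). DR pool 6 lay apart in this group, and without it the median was -0.39. The groups leading in fat body and gut also had medians below 0 in heart, at -0.37 and -0.29. With members chosen from AL pools these were -0.36 and -0.01. Neither passed camera with an estimated correlation (adjusted p = 0.59 and adjusted p = 0.608). The position slope, the log2 level per kb of probe position along a transcript, went from 0.441 ± 0.0110 (SD, n = 5) to 0.519 ± 0.0163 (SD, n = 6) in heart (exact permutation test, adjusted p = 0.00758). In fat body it went from 0.387 ± 0.0122 to 0.407 ± 0.00866 (SD, n = 6; exact permutation test, adjusted p = 0.0152).

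In muscle no named gene passed as higher on DR food and 7 fell (n = 6 per food). The gene fend fell 3.15-fold (-1.66 ± 0.18 SE; adjusted p = 2.54e-11) and SuUR 1.87-fold (-0.90 ± 0.13; adjusted p = 2.56e-08). Falls of 0.78 ± 0.21 in sle, 0.47 ± 0.10 in HDAC3 and 0.41 ± 0.13 in rdx were separated like those of fend and SuUR. With the within-group axis as a covariate these 3 genes were at -0.55 (adjusted p = 0.053), -0.16 (adjusted p = 0.124) and -0.29 (adjusted p = 0.124). Wdr24 (-0.35, adjusted p = 0.0147) and Uba1 (-0.17, adjusted p = 0.0236) lost their calls under the same covariate (-0.20 and -0.06) and without DR pool 1 or 6, Wdr24 also without DR pool 2 and Uba1 without AL pool 5. Left-out pools moved Wdr24 between -0.47 and -0.25 and Uba1 between -0.19 and -0.15. FBtr0087854 rose by 2.19 ± 0.11 and FBtr0088192 by 1.97 ± 0.20. The 481 transcripts leading in muscle rose in muscle by a median of 0.24 (177 higher, 6 lower; adjusted p = 2.59e-08, and adjusted p = 0.301 with an estimated correlation). Medians of the same group in the other tissues ran from 0.20 in germ line to 0.64 in neuron, and none passed with an estimated correlation.

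In neurons, Fatp1 rose 2.71-fold on DR food (1.44 ± 0.16 SE; adjusted p = 2.21e-12; n = 5 AL and 6 DR pools) with separated pools, and alpha-Spec rose by 0.84 ± 0.15 (adjusted p = 1.2e-06). Of the 14 named genes 9 fell. SuUR fell 2.70-fold (-1.43 ± 0.14; adjusted p = 1.72e-15), sle 2.69-fold (-1.43 ± 0.22) and HDAC3 2.31-fold (-1.21 ± 0.11; adjusted p = 9.49e-17). Wdr24 fell by 0.79 (SE 0.13), rdx by 0.78 (SE 0.14) and Uba1 by 0.34 (SE 0.07), all separated. LanA fell by 1.12 (SE 0.25; adjusted p = 5.66e-05), but its DR pools spread with an SD of 1.31, the pools overlapped, and a fit on neuron arrays alone gave an adjusted p of 0.0827. The fall of mio, 0.42, was -0.16 (adjusted p = 0.277) with cyclic loess. That of kis, 0.41, had an adjusted p of 0.0836 in the fit on neuron arrays alone, and its size without DR pool 5 was -0.23 (adjusted p = 0.0177). FBtr0087854 rose by 4.20 ± 0.11 and FBtr0111188 by 3.79 ± 0.21.

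The 462 transcripts leading in neurons rose in neurons by a median of 2.61, a 6.10-fold change. Of these, 450 rose and 3 fell (adjusted p = 0.0104 with an estimated correlation), and the mean level on the scale shared between tissues went from 9.31 ± 0.27 (SD, n = 5) in AL to 11.70 ± 0.33 (SD, n = 6) in DR. Members chosen from AL pools alone, 96 transcripts, gave a median of -1.37 and did not pass (adjusted p = 0.433). Members chosen from DR pools alone, 969 transcripts, gave 2.47. The group of 462 also had medians above 0 in the other 6 tissues, from 0.28 in heart to 0.79 in tubule, where 354 rose and 16 fell. With members chosen from AL pools they ran from -0.58 in muscle to 0.03 in fat body. None of these 6 passed with an estimated correlation (adjusted p = 0.133 in tubule). In neurons the transcripts leading in heart had a median of 1.18 (48 higher, 5 lower), and one of 0.33 with members chosen from DR pools. Those leading in germ line had a median of -0.45 (62 higher, 252 lower), and one of -0.29 with members chosen from AL pools. With an estimated correlation the groups of 1.18 and -0.45 had adjusted p = 0.301 and adjusted p = 0.651 in camera. Mean profiles of neuron AL correlated across transcripts at 0.938 with germ line AL, 0.929 with heart AL, 0.921 with muscle AL and 0.898 with neuron DR. The closeness to germ line AL is therefore not particular to that tissue. Transcripts are not independent replicates.

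**Figure D3:**
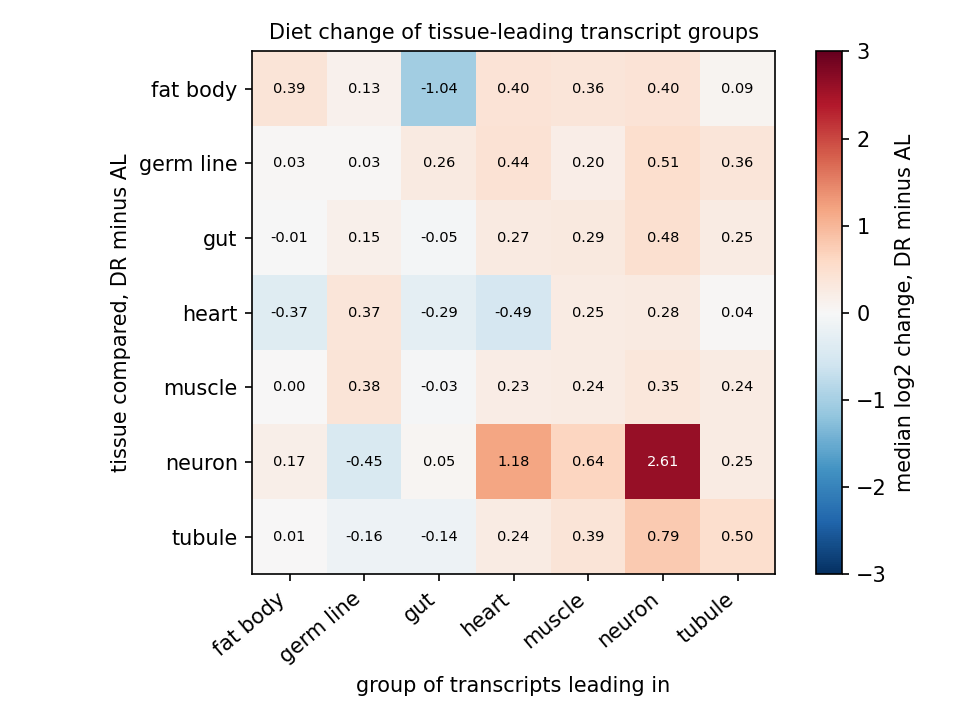
Each cell gives the median log2 change, DR minus AL, of a group of transcripts leading in 1 tissue (columns) in each tissue compared (rows), with red for higher and blue for lower on DR food. The neuron group in neuron stood at 2.61 and the gut group in fat body at -1.04, the 2 cells that passed with an estimated correlation.

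In tubule, Fatp1 rose 1.92-fold (0.94 ± 0.16 SE; adjusted p = 5.64e-07; n = 6 per food) and alpha-Spec by 0.76 ± 0.15 (adjusted p = 1.26e-05), both separated. The gene fend fell 3.01-fold (-1.59 ± 0.18; adjusted p = 3.77e-11), sle 2.27-fold (-1.18 ± 0.21) and NaPi-III 2.03-fold (-1.02 ± 0.20; adjusted p = 1.09e-05), all separated. LanA (0.50, adjusted p = 0.0891) passed as higher in the fit on tubule arrays alone (adjusted p = 0.00171), with array weights (0.58, adjusted p = 1.65e-05) and under 3 other alternatives. SuUR fell by 0.47 (SE 0.13), and without AL pool 4 its change was -0.29 (adjusted p = 0.042). AL pool 4 stood apart in this group, with a mean correlation of 0.969 with its fellow pools against 0.989 to 0.991 for the others. Without it rdx (-0.44) was at -0.29 (adjusted p = 0.0692) and HDAC3 (-0.24, adjusted p = 0.048) at -0.14 (adjusted p = 0.297). HDAC3 also lost its call without AL pool 6 or any 1 DR pool, with values from -0.28 to -0.14. FBtr0073231 was below the control probes on all AL arrays and rose at least 10.7-fold, and FBtr0088192 rose by 4.37 ± 0.20. The 551 transcripts leading in tubule had a median of 0.50 (283 higher, 58 lower; adjusted p = 6.45e-10, and adjusted p = 0.378 with an estimated correlation). AL pool 4 also lay apart in this group, and without the 4 arrays standing apart the median was 0.33 (253 higher, 87 lower). With members chosen from AL pools it was 0.27. The position slope was higher in DR (0.513 ± 0.0107, against 0.467 ± 0.00916 in AL, SD, n = 6; exact permutation test, adjusted p = 0.00758).

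The diet response differed between tissues for 14971 transcripts, 90.0% of those tested. Each tissue was sampled through its own driver line, so tissue and line cannot be told apart. Tissues also differed in the narrowing of the gap between dim and bright transcripts (0.83 in germ line, -0.01 in fat body), which enters this count. Among the 14 named genes 13 passed this test of the difference, with rdx the exception (adjusted p = 0.0549). LanA, higher in fat body and gut and lower in neuron, had an adjusted p of 1.62e-07. The GATOR2 genes mio and Wdr24 both rose in fat body and fell in neuron (adjusted p = 3.14e-07 and adjusted p = 4.2e-06 for the difference between tissues). Fatp1 rose in fat body, neuron and tubule (adjusted p = 5.69e-08), with values from 0.02 in gut to 0.20 in germ line in the other 4. Fatp1 passed as higher with array weights in germ line (0.51, a value that rests mostly on 1 DR pool) and heart (0.26, adjusted p = 0.00993). With cyclic loess it passed in germ line (0.52, adjusted p = 0.00432) and muscle (0.36, adjusted p = 0.0489). His4r rose in fat body and fell in germ line (adjusted p = 2.29e-06). The genes SuUR, fend and sle fell in 5 tissues each and HDAC3 in 6, and alpha-Spec rose in 5. Of 52 calls of a named gene in a tissue, 28 held under every alternative fit and without any single pool, and 22 of these also reached 1.5-fold. Of the 46 values of named genes that did not pass, 26 passed in the same direction under at least 1 alternative fit and 12 under at least 3. Besides LanA in germ line, heart and tubule these 12 were NaPi-III in muscle (-0.44), neuron (-0.39) and fat body (-0.41), SuUR in germ line (-0.26), HDAC3 in gut (-0.23), kis in muscle (-0.21), fend (-0.28) and rdx (-0.25) in heart, and mio in tubule (0.22). Without fat body DR pool 6 NaPi-III passed there at -0.64 (adjusted p = 0.00405).

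**Figure D4:**
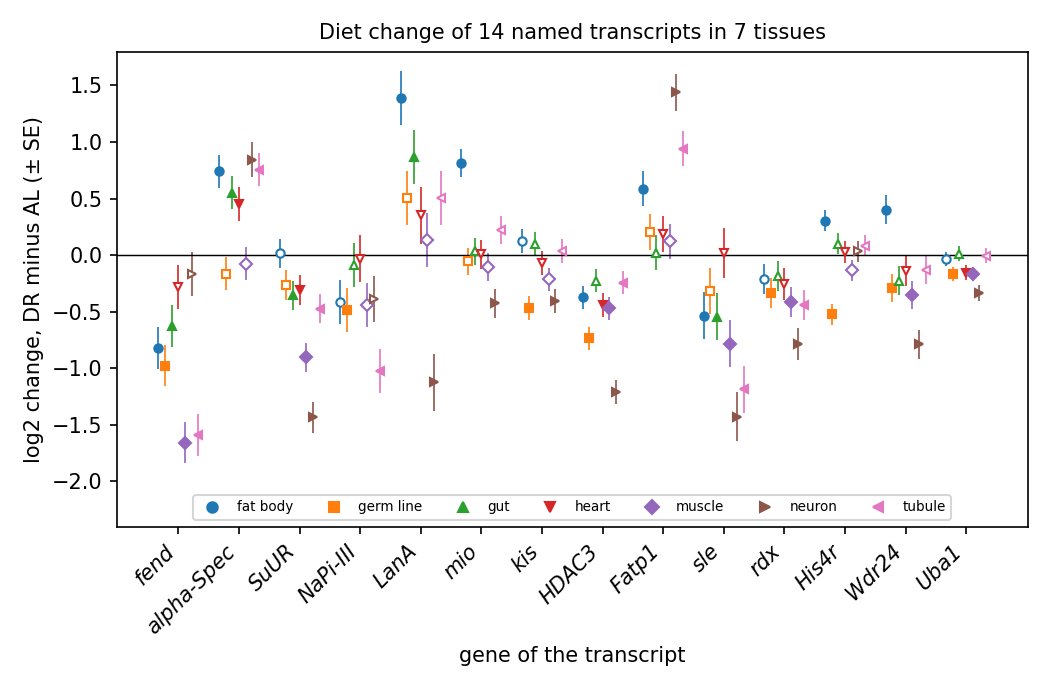
Points give the log2 change, DR minus AL, of the transcript of each of 14 named genes in 7 tissues, with bars for the SE and filled symbols for an adjusted p below 0.05. The largest fall was that of fend in muscle (-1.66) and the largest rise that of Fatp1 in neuron (1.44).

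Many transcripts also changed in the same direction in several tissues. The mean of the 7 effects passed for 13398 transcripts, 6839 higher and 6559 lower on DR food. Transcripts called higher in all 7 tissues numbered 465, against 0.845 if the calls of the tissues were independent, and those called lower in all 7 numbered 571, against 1.02. Any shift shared by the pulldowns, such as that of dim against bright transcripts, also breaks independence. Whether RNA from other tissues in the pulldowns adds to the shared calls was not tested. At least 4 tissues called 2739 transcripts higher and 3657 lower. Calls in opposite directions in different tissues were found for 4286 transcripts (25.8%), and 469 were called in none. Diet changes correlated most strongly across transcripts between germ line and muscle (Pearson's r = 0.791), germ line and heart (0.750) and heart and muscle (0.725), followed by neuron and tubule (0.669) and fat body and gut (0.621). With the within-group axis as a covariate the values for germ line, heart and muscle were lower, at 0.540, 0.502 and 0.489 in the same order, and that for neuron and tubule (0.660) was the highest of the 21. Without that covariate the lowest was that of fat body and germ line (0.288), and with it that of heart and neuron (0.322). These r are across transcripts, which are not independent replicates.

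Each tissue had its own set of enriched messages. Germ line had 2799 enriched transcripts, muscle 1918, tubule 1817, fat body 1807, gut 1447, neuron 1325 and heart 688. Among the named genes, sle (1.65 ± 0.11 SE) and SuUR (1.25 ± 0.07) were enriched in germ line, fend in neuron (1.49 ± 0.11), NaPi-III in neuron (1.00 ± 0.11) and Fatp1 in fat body (1.16 ± 0.09), each as the log2 excess over the mean of the other 6 tissues. With the deposited values, which are not scaled between tissues, the counts were 7668 in germ line, 290 in heart, 2946 in muscle and 3314 in neuron. With each array's median subtracted, fat body had 2784, and sle (0.82) and SuUR (0.54) were less than 2-fold above the other tissues in germ line. With position slope and control probe level as covariates fend (0.78) and NaPi-III (0.80) were less than 2-fold above in neuron, and NaPi-III (0.95) also with median polish and (0.94) with array weights.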

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

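The tests of the dim and bright transcripts and of the neuron leading group in the paragraphs below were chosen after the results were seen, as were the leading groups and all tests of them, regroupings included, while the other counts over regroupings of the arrays were planned.

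The transcripts leading in neurons rose by a median of 2.61 in the neuron pulldowns on DR food. Germ line arrays under the neuron AL label are argued against, since the lowest germ line AL array lay 1.05 above the highest neuron AL array in 581 transcripts that led in germ line, chosen from DR pools alone. A lower share of neuronal RNA in the AL pulldowns, made up evenly by the other tissues, would lower their groups on DR food alike. Such a common fall was not seen. The heart group had a mean change of 1.19 and the germ line group one of -0.55. Over 3 choices of members the 2 differed by at least 1.23 (SE 0.20), and the heart group rose by at least 0.55 (SE 0.06). This cannot decide the question, because RNA from 1 tissue alone need not lower every group. Only the germ line group, among those of the other tissues, had a mean change below 0 with members chosen from both foods. This fall depends on the choice of members. The mean change was -0.03 (SE 0.10) with members from AL pools and -0.74 (SE 0.13) with members from DR pools. A lower neuronal share in AL and a change in 1 of the other cell types therefore stay open. The choice of members stays open, because the 96 chosen from AL pools had a median of -1.37 (33 higher, 59 lower) and the 969 chosen from DR pools one of 2.47, and each choice works toward its own result, so that it and an effect of food on neurons cannot be told apart. A difference in how the pulldowns recovered neuronal ribosomes was not tested.

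Dim transcripts rose and bright ones fell on average on DR food, most in germ line, heart, muscle and neuron, the 4 tissues weighed here, while the gap narrowed less in gut (0.14) and tubule (0.16). A lower 95th percentile of the control probes as the whole cause is argued against, because the gap still narrowed in these 4 by at least 0.45 (SE 0.13, in heart) with that level as a covariate. In neuron that level was higher on DR food, by 0.12. The control probes were normalized together with the transcripts, so their level is not an independent measure of background. The test covers that level alone and not the background before normalization. The SEs here pool the spread of all 14 groups. Within groups the control probe level correlated with the leading within-group axis at 0.938 in germ line, 0.921 in muscle, 0.778 in heart and 0.069 in neuron. It is therefore not separate from the variation between pools weighed below in germ line, muscle and heart. A coverage change along the transcripts of like size in heart and muscle is argued against by the position slope, whose change in heart exceeded that in muscle by 0.0918 (SE 0.0168). Germ line and neuron were not in this test, and coverage changes that differ between tissues stay open. Variation between pools that also runs within groups may account for the pattern in heart and muscle, where the leading axis of within-group variation in the other 6 tissues left changes of 0.07 (SE 0.04) and 0.11 (SE 0.05). In germ line the same correction left 0.80 (SE 0.12), but that axis correlated with the germ line diet change at only 0.0653 across transcripts, and in neuron it left 0.22 (SE 0.04) of 0.48 (SE 0.14) with a correlation of 0.178, so that such variation and an effect of food cannot be told apart in these tissues.

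Chance in the grouping of arrays is argued against for the diet counts, since in each tissue 1 of 100 splits, the real one itself, gave a count as large. The real count and the highest of the other splits were 6256 and 4016 in fat body, 11807 and 11203 in germ line, 5969 and 4724 in gut, and 8687 and 7145 in heart. They were 9162 and 7881 in muscle, 10977 and 10269 in neuron, and 6624 and 4689 in tubule. The highest other split had 1 array out of place in heart and neuron, 2 in fat body, gut, muscle and tubule, and 4 in germ line. For the difference between tissues the values were 14971 and 11090, and for the mean effect 13398 and 976. Enriched transcripts numbered 1807 against 0 in fat body, 2799 against 372 in germ line, 1447 against 488 in gut, 688 against 374 in heart, 1918 against 149 in muscle, 1325 against 492 in neuron, and 1817 against 538 in tubule, again 1 split of 100 each. For the tests of leading groups 2 of 100 splits gave as many calls as the real 36, the highest other split gave 38 and the median 29, which leaves calls at the preset correlation weak as evidence for a single group.

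The diet effect differed between the tissues for 14971 transcripts and for these named genes, each with the adjusted p of the difference. The values were 2.52e-07 for fend, 4.12e-06 for alpha-Spec, 1.81e-09 for SuUR, 0.0235 for NaPi-III, 1.62e-07 for LanA, 3.14e-07 for mio, 0.000248 for kis and 4.49e-08 for HDAC3. They were 5.69e-08 for Fatp1, 0.000193 for sle, 2.29e-06 for His4r, 4.2e-06 for Wdr24 and 0.00511 for Uba1. Transcripts of CG16974 (0.00025) and CG31178 (0.0338), genes known by a number alone, also differed. CG16974 was lower in gut by 0.70 and in fat body by 0.59, with every DR pool below every AL pool. It also passed in germ line, heart, muscle and neuron, but with cyclic loess it was at -0.04 in germ line, -0.09 in heart and -0.01 in neuron. In neuron it was at -0.12 (adjusted p = 0.196) without DR pool 5. In heart the call was lost under 5 of the 11 removals of a single pool. CG31178 passed in muscle at 0.40, but was at 0.14 with cyclic loess and 0.21 with the within-group axis as a covariate.

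In 18 of 126 tests, each of 1 measure in 1 group of pools, 1 pool lay far from its fellows, and AL pool 4 of tubule gave 7 of these. The measures share the same 14 groups and are not independent, so the number due to chance, 6.3 for independent tests, is not known. The figure for each is the gap to the nearest pool as a share of the group's range. For the correlation with the rest of the group it was 0.647 in germ line DR (pool 6), 0.79 in heart DR (pool 6), 0.65 in muscle DR (pool 4), 0.742 in neuron DR (pool 5) and 0.891 in tubule AL (pool 4). Pool 6 of germ line DR also had 80.9% of transcripts above the control probes against 95.8% to 99.4% (0.807). The control probe level of pool 6 of heart DR (0.707) and the position slope of pool 5 of neuron DR (0.691) stood apart as well.

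Among leading groups the figure was 0.768 for the germ line group in germ line AL (pool 5), 0.838 for the heart group in heart DR (pool 6), 0.901 for the tubule group in tubule AL (pool 4) and 0.758 for the tubule group in tubule DR (pool 1). The tubule group stood at 10.84 in AL pool 4 against 11.68 to 11.77 in the other AL pools. Named genes in that pool gave 0.755 for fend and 0.755 for alpha-Spec, 0.702 for NaPi-III, 0.739 for Fatp1 and 0.868 for sle, and sle in muscle DR gave 0.66 (pool 1).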

How the results depend on the processing

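Covariates, cyclic loess, later probes, the background filter, the removal of pools standing apart, the 1.5-fold minimum and joint adjustment on named genes and all tests of leading groups were chosen after seeing the data, and the other alternatives were planned. The diet, interaction and mean-effect counts stayed within 1.5 times their values apart from those given here. With a 1.5-fold minimum the diet counts were 3334 in fat body, 6971 in germ line, 2916 in gut, 5270 in heart, 5055 in muscle and 3839 in tubule, since fewer transcripts can pass. With the within-group axis as a covariate they were 4842 in germ line, 5053 in heart and 5566 in muscle. That axis correlated with the diet change across transcripts at -0.785, -0.657 and -0.706 in these tissues. The covariate may therefore also remove an effect of food. Enrichment counts with deposited values were 7668 in germ line, 290 in heart, 2946 in muscle and 3314 in neuron, and 2784 in fat body with array medians subtracted; the cause was not tested. Calls of leading groups fell to 2 with an estimated correlation. The neuron group in neuron reversed with members from AL pools (-1.37). Values of named genes that reversed were mio in germ line with array weights (0.13) and cyclic loess (0.30), His4r in heart with slope and control level as covariates (-0.20), and CG31178 (-0.30) and Wdr24 (0.035) in germ line with cyclic loess; the cause was not tested. Array weights did not fully converge. They gave germ line DR pool 3 a weight of 71.7, against 0.0358 to 0.587 for the other germ line DR pools. Germ line values with array weights, that of mio included, therefore rest mostly on 1 DR pool.

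Without each pool in turn the diet counts ran from 5751 to 6189 in fat body, 10464 to 12465 in germ line, 5102 to 6201 in gut, 7802 to 8599 in heart, 7774 to 9627 in muscle, 10615 to 11134 in neuron and 5660 to 6571 in tubule. The interaction count ran from 14734 to 15560 and the mean effect from 13290 to 13684. Of 1312 values of named transcripts without a pool, 1240 kept their side of the threshold, 62 lost a call and 10 gained one. Of 52 calls of named genes, 24 were lost under some alternative fit, 27 lay below 1.5-fold and 1 was lost with the adjustment over the 7 contrasts together, which makes 30 in all. Without the 4 arrays standing apart the diet counts were 7367, 12980, 7248, 9932, 10642, 11187 and 6441 in the tissue order above.

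Pool numbers did not pair the samples throughout, since the correlations of like-numbered pools ran from -0.443 to 0.773 and no tissue had every pair above 0.1. Still, their median exceeded that of unlike-numbered pools in every tissue but neuron (-0.003 against 0.020). The medians were 0.301 against -0.190 in germ line, 0.260 against -0.080 in gut and 0.293 against 0.022 in muscle. A partial effect shared by like-numbered pools therefore stays open. With the pool number as a replicate block the diet counts were 6748 in fat body, 12192 in germ line, 6492 in gut, 8366 in heart, 9666 in muscle, 11387 in neuron and 7059 in tubule, with 15219 for the interaction and 13515 for the mean effect. Not every pool correlated best with its own number in any tissue, with at most 3 doing so. The tests of gene lists and their alternatives were not run, for want of gene names. Signal over background limits dim transcripts, since only 62.8% lay above the control probes in fat body AL.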

Other observations

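The values below on leading groups rest on groups and tests chosen after the results were seen. The transcripts leading in fat body had a median of 0.39 in fat body (193 higher, 46 lower) and -0.37 in heart (48 higher, 187 lower). Those leading in germ line had a median of 0.37 in heart (229 higher, 32 lower). None of these tests passed with an estimated correlation, with adjusted p-values from 0.477 to 0.59.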
